A study of Mus musculus with 20 samples.

How the data were processed

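Input RNA and m6A-immunoprecipitated RNA of 10 mouse hearts were sequenced, 5 db/db and 5 db/+ animals, as 20 libraries. Per the labels' protocols, hearts were frozen in liquid nitrogen, RNA was harvested with Trizol, messenger RNA was purified by its poly(A) tail, and libraries were built with a KAPA stranded mRNA kit. Groups were taken from the sample titles, which name the genotype and a replicate number. The genotype field calls the db/+ animals wild type, and the titles were followed. Sexes and ages of the animals were not used here. The submitters' processing notes list FastQC 0.11.7, Trimmomatic 0.32, HISAT2 2.1.0 and the build mm9, without their roles. The program that computed FPKM and the peak caller are not given in the sources used here.

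The expression table holds FPKM deposited by the authors, fragments scaled to transcript length and library size, for 11856 protein-coding genes in the 10 input libraries. One more line of the table was empty and was skipped. The lowest value of the larger genotype mean over genes was 0.5 FPKM, so the table had been filtered on low values before it was deposited. Among the 500 lowest genes, ratios between libraries showed no steps of whole reads (2.6% of genes lay within 1% of the most common ratio), so the depth of the libraries is unknown and no count test was run. Low values carry more error than high ones, which the trend in the limma fit takes up only on average. Sequencing of poly(A) RNA leaves the mitochondrial transcripts in, and they took 33.5% to 44.7% of the FPKM of a library, so that a shift in their share moves the FPKM of all other genes. Gene positions fit GRCm38: of 11500 genes matched by symbol and chromosome to the reference gene table of GRCm38, 89.9% had a start or end within 50 bp. Positions are given as deposited by the authors, counted from 1, with no conversion between builds.

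The peak lists, per the file headers, give for each animal the position, exon blocks, gene, fold enrichment and p-value of each peak as the authors' peak caller gave them, called per animal and not on pooled samples. The fold is a ratio of immunoprecipitated to input signal made by the authors and ranged from 1.05 to 241. The p-value column deposited by the authors reached 0.00513. These values were used only to rank or filter peaks within a list. The 146953 lines of the 10 lists held 5117 repeats of the same position (3.5%), which were removed. Peaks of a heart that overlapped at other positions were kept as distinct peaks, also in the shares by part of the transcript. A peak was set to a 5′ untranslated, coding or 3′ untranslated part by the annotation in the lists.

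The main tests were fixed before the data were examined, while the comparison of peak shares over parts of the transcript and the tests named as such in the closing section were chosen later. Differential expression used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend) on log2(FPKM + 1), for genes with a mean of at least 1 FPKM over the 10 libraries, 10344 genes, as db/db minus db/+. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The pseudocount of 1 understates fold changes of low genes. There were 36 fixed gene lists with 455 different genes, and camera tested the 29 lists with at least 3 tested members, with a preset inter-gene correlation of 0.01 and adjustment over the 29. None of the 9 lists that passed camera also passed with an estimated correlation. The other 7 lists had fewer than 3 tested members and no call: the m6A erasers with 2, neutrophil, brown adipocyte and Schwann cell and nerve with 2 each, cell cycle with 1, and lymphocyte and skeletal muscle with 0. Each list count was also adjusted over the list alone.

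The genes named were set by a rule: a pair of genes tied to the db strain, the m6A writers, erasers and readers, the 10 largest rises and falls among called genes with no overlap between genotypes, up to 4 members of each list with the smallest p, and up to 6 gained and 6 lost peak regions ordered by the difference in animals and then by fold. Predicted genes with no name were passed over, 1 rise and 5 falls. Some genes that the rule names are not reported here. Some further members of lists are named after their values were seen: Fabp3, Cd36, Retsat, Acadl, Etfdh and Eci2, which complete the called members of their lists, and Adipoq.

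Counts of peaks, of genes with a peak and median peak lengths were compared with exact two-sided permutation tests over the 252 assignments of 5 against 5 animals. Regions were merged over animals where exon blocks overlapped by at least 1 bp on one strand. A region was counted as differing with a peak in at least 4 animals of one genotype and at most 1 of the other, and Fisher's exact test was run per region with adjustment over all regions. List similarity was the mean Jaccard index in bp within minus between genotypes, with an exact one-sided permutation test. Expression of genes with gained or lost regions was tested with limma cameraPR against genes with a peak region. For counts over many genes or regions, 100 of the 126 splits of the animals into 5 and 5 were drawn with a fixed seed. Peak tables were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

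The expression steps were tested on simulated data for db/db against db/+ with 10344 genes and 200 planted changes. They recovered 86% of the genes planted at 1.5-fold and 91% of those at 2-fold, made 189 calls of which 12 were not planted, and gave 0 calls of the wrong sign. Each gene was drawn independently, so shifts shared by many genes of a library were not simulated. No change under 1.5-fold was planted, so these rates say nothing of smaller changes. The region steps were tested on simulated peak lists of 5 against 5 animals with 3000 sites: 100% of planted gained and lost regions were recovered and 88 regions with no planted difference also met the rule. Planted sites had a peak in all animals of one genotype and none of the other, so they met the rule by design. Their recovery says nothing of regions found in only some animals. The peak rates of the other sites were drawn evenly and not from the real lists.

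Alternatives tried were other pseudocounts, filters and scalings, no trend, array weights, a replicate block, a fold limit, each animal left out in turn, estimated list correlations and fry, stricter peaks, equal numbers of top peaks, other overlaps and presence rules. After the data were seen, fits without db/+ 5 and db/db 5, with adipocyte or mitochondrial covariates and with the nuclear total set equal were added.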

Results

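Hearts of 5 db/db mice and 5 db/+ mice on the C57BL/6 background were profiled, which gave 20 libraries: an input RNA-seq library and a library of RNA pulled down with an antibody to N6-methyladenosine (m6A) for each of the 10 animals. Mice homozygous for the db allele lack a working leptin receptor and become obese and diabetic, while heterozygous db/+ mice are the usual lean controls of that strain. The comparison addressed how transcript levels and the m6A marks on messenger RNA differ between diabetic and healthy hearts. Expression was read from FPKM values of the 10 input libraries over 11856 protein-coding genes, of which 10344 had a mean of at least 1 FPKM and were tested. The m6A marks were read from 10 peak lists, 1 per animal, with 8462 to 20021 distinct peaks each. FPKM values carry no read counts, so the depth of each library is unknown. The FPKM of the listed genes summed to between 307868.8 and 340468.3 per library. Each animal is a separate sample in the labels, so n = 5 per genotype throughout and errors are SDs of FPKM or standard errors of the log2 fold change.

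The leptin receptor gene itself was not analysed here, so no gene in the data checked the genotype labels.

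Among called genes whose values did not overlap between genotypes, Tfrc was among the largest rises in db/db hearts, and Scgb1c1 and Cyp2e1 fell most. Tfrc, the transferrin receptor that takes up iron, rose from 5.02 ± 1.61 FPKM in db/+ to 19.3 ± 7.49 FPKM in db/db (SD, n = 5; log2 fold change 1.73, SE 0.23, adjusted p = 0.00355). The largest of these falls was in Scgb1c1, a secretoglobin, from 17.5 ± 3.01 to 2.74 ± 1.09 FPKM (log2 fold change -2.35, SE 0.203, adjusted p = 0.000348). Cyp2e1, a cytochrome P450 of ethanol and fatty acid metabolism, fell from 9.28 ± 6.69 to 1.16 ± 0.694 FPKM (log2 fold change -2.03, SE 0.417, adjusted p = 0.0274).

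Across the genes tested with limma, 133 were higher and 178 were lower in db/db hearts at a Benjamini-Hochberg adjusted p under 0.05, 311 in all. Over all tested genes, the 5 values of one genotype did not overlap the 5 of the other in 663 (6.41%), where chance gives 0.79%. Of the called genes, which their small p makes likely to separate, 277 did so. Most called changes were small. On the scale of log2(FPKM + 1), the median absolute log2 fold change of the called genes was 0.43, and 16 genes changed by at least 2-fold. The pseudocount shrinks the folds of low genes, so the count in FPKM itself would be larger. Gcat, at 3.43 FPKM in db/+ and 1.30 FPKM in db/db, is not among the 16 (log2 fold change -0.95). Besides Tfrc, the 10 largest rises among called genes with no overlap between genotypes included Scd4, Kcnk1, Chrna2, Vsig4, Edn3, Klk1b26, Acot1 and Acot2. Vsig4, a complement receptor of tissue macrophages, rose from 3.55 ± 0.79 to 9.94 ± 2.50 FPKM. Edn3, which encodes an endothelin, rose from 0.685 ± 0.326 to 2.99 ± 0.742 FPKM. Chrna2, a nicotinic acetylcholine receptor subunit, had a log2 fold change of 1.31 (SE 0.122). Scd4, a stearoyl-CoA desaturase, had a log2 fold change of 1.54 (SE 0.168), and Klk1b26, a kallikrein, one of 1.24 (SE 0.208). Scd4 and Klk1b26 have near-identical relatives that can share reads, so their values are uncertain.

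Besides Scgb1c1 and Cyp2e1, the 10 largest falls among called genes with no overlap between genotypes were in Cyp1a1, Kcnip2, Gcat, Pcx, Slc25a33, Klhl33, Chac1 and Nrep. Kcnip2, the accessory subunit of the fast transient outward potassium current, fell from 29.4 ± 5.06 to 13.7 ± 1.98 FPKM (log2 fold change -1.04, SE 0.128, adjusted p = 0.0028). Pcx, pyruvate carboxylase, fell from 8.17 ± 1.27 to 3.77 ± 0.767 FPKM, and Slc25a33, a mitochondrial pyrimidine nucleotide carrier, from 14.97 ± 1.81 to 7.42 ± 1.39 FPKM. Gcat, an enzyme of threonine breakdown, had a log2 fold change of -0.95 (SE 0.086), Klhl33 of -0.92 (SE 0.149) and Nrep of -0.88 (SE 0.122). Some of these largest rises and falls had values near the floor of the table in a genotype. Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, was listed at 0 in 4 db/db hearts and at 0.071 FPKM in the other, against 2.095, 1.51, 1.52, 2.32 and 2.59 FPKM in the db/+ hearts. Kcnk1, a potassium channel, was listed at 0 in 2 db/+ hearts and at 0.109, 0.085 and 0.146 FPKM in the others, against 3.59, 1.39, 1.49, 1.15 and 2.73 FPKM in the db/db hearts. Klk1b26 was listed at 0 in db/+ 1.

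The count of called genes moved with the choice of libraries and covariates. It was 112 to 315 when single libraries were left out, 189 with a score of adipocyte markers as a covariate and 137 with the mitochondrial share of FPKM as one. The balance of directions depended on scaling: 42.8% of the calls were rises with the authors' scaling, against 161 rises and 113 falls (58.8% rises) with the medians of the libraries set equal. It also depended on the hearts used. With the authors' scaling there were 67 rises and 60 falls without db/db 1, and 145 and 131 without db/db 5. Falls stayed ahead without any other single library. Without db/+ 5 and db/db 5, chosen after seeing the data, there were 201 rises and 168 falls.

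**Figure D1:**
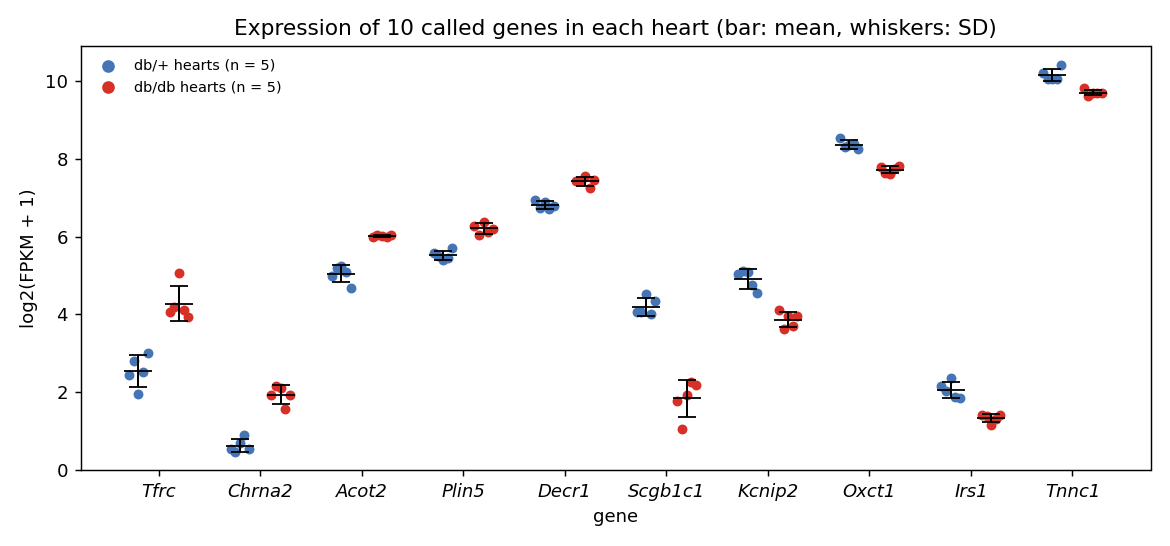
Expression of 10 called genes in each heart, as log2(FPKM + 1) on the vertical axis. Points are single hearts (5 db/+ in blue, 5 db/db in red), the bar is the mean and the whiskers are the SD. The db/db hearts lie above all db/+ hearts for Tfrc (log2 fold change 1.73), Chrna2, Acot2, Plin5 and Decr1 and below them for Scgb1c1, Kcnip2, Oxct1, Irs1 and Tnnc1 (log2 fold change -0.45).

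In genome coordinates that fit the mouse build GRCm38, Tfrc (ENSMUSG00000022797.15) lies on chromosome 16 from 32608920 to 32632794 on the plus strand. Scgb1c1 (ENSMUSG00000038801.6) lies on chromosome 7 from 140845547 to 140846769 on the plus strand, downstream of Cyp2e1 (ENSMUSG00000025479.9), which spans 140763739 to 140774987 on the same chromosome and strand. Kcnip2 (ENSMUSG00000025221.15) lies on chromosome 19 from 45791839 to 45816061 on the minus strand.

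Genes that PPAR-alpha, the fatty acid sensing nuclear receptor, is known to switch on were higher in db/db hearts. Of 17 PPAR-alpha target genes tested, 9 rose and none fell, 12 rose when adjusted over the list alone, and all 17 fold changes were positive with a mean of 0.57. That of Pdk4 (0.46, SE 0.404) leaned on db/+ 5, at 88.6 FPKM against 399 to 563 FPKM in the other 9 hearts. Acot2, a mitochondrial acyl-CoA thioesterase, rose from 32.3 ± 4.85 to 63.8 ± 1.28 FPKM (log2 fold change 0.97, SE 0.094, adjusted p = 0.000486). Acot1, its cytosolic relative, had a log2 fold change of 1.07 (SE 0.139), and these paralogs can share reads. Plin5, a coat protein of lipid droplets, rose from 45.0 ± 3.91 to 73.1 ± 6.76 FPKM (log2 fold change 0.69, SE 0.079). Fabp3, the cytosolic fatty acid carrier of heart muscle, and Cd36, a fatty acid transporter of the cell surface, had log2 fold changes of 0.31 (SE 0.054) and 0.45 (SE 0.082). Retsat was called as well, with a log2 fold change of 0.37. The PPAR-alpha list passed camera with the preset correlation (adjusted p = 7.09e-16). Its adjusted p was 0.0845 with an estimated correlation.

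Enzymes of fatty acid oxidation were also higher in db/db hearts. Of 22 tested, 7 rose and none fell, 14 rose when adjusted over the list alone, and 21 fold changes were positive with a mean of 0.24. Decr1, which reduces intermediates of unsaturated fatty acids, rose from 112 ± 7.74 to 171 ± 13.1 FPKM (log2 fold change 0.61, SE 0.069, adjusted p = 0.00184). Slc25a20, the carnitine-acylcarnitine carrier, rose by 0.50 on the log2 scale (SE 0.069). Ech1, a dienoyl-CoA isomerase, rose by 0.48 (SE 0.071) and Acaa2, a thiolase, by 0.41 (SE 0.067). Acadl, Etfdh and Eci2 were the other called members, at 0.30, 0.34 and 0.33. Slc25a20 and Ech1 stood in both lists. These enzymes passed camera as a list (adjusted p = 3.67e-14), and its adjusted p was 0.243 with an estimated correlation.

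Ketone body metabolism went both ways. Of 6 genes tested, 1 rose and 1 fell. Oxct1, the enzyme that activates ketone bodies for oxidation, fell from 328 ± 26.6 to 209 ± 13.1 FPKM (log2 fold change -0.65, SE 0.067, adjusted p = 0.000936). Bdh1, beta-hydroxybutyrate dehydrogenase, had 26.4 ± 5.89 FPKM in db/+ and 14.1 ± 4.83 FPKM in db/db (adjusted p = 0.068). When adjusted over the list alone, 2 genes rose and 2 fell. The list's mean was 0.13 and its median -0.06, and it did not pass camera (adjusted p = 0.778; 0.865 with an estimated correlation).

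Of 19 genes of glucose uptake and glycolysis tested, 2 fell in db/db hearts and none rose, 7 fell when adjusted over the list alone, and the mean was -0.16. Slc2a4, the insulin-responsive glucose transporter GLUT4, fell from 67.9 ± 5.03 to 48.3 ± 3.69 FPKM (log2 fold change -0.48, SE 0.071, adjusted p = 0.0059). Eno3, muscle enolase, fell by 0.40 on the log2 scale (SE 0.069, adjusted p = 0.0134). Pfkfb2 and Ldhb had log2 fold changes of -0.53 (SE 0.134, adjusted p = 0.0561) and -0.23 (SE 0.062, adjusted p = 0.0728). As a list these genes passed camera (adjusted p = 0.00564), and its adjusted p was 0.482 with an estimated correlation.

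Of 16 genes of insulin signalling, 2 fell: Irs1, the insulin receptor substrate, from 3.20 ± 0.628 to 1.54 ± 0.177 FPKM (log2 fold change -0.72, SE 0.101, adjusted p = 0.00518), and Akt1, a kinase of the insulin cascade, from 33.1 ± 4.44 to 25.0 ± 1.19 FPKM (log2 fold change -0.39, SE 0.084, adjusted p = 0.035). Foxo3 and Pik3r1 had log2 fold changes of -0.35 (SE 0.085, adjusted p = 0.0528) and 0.40 (SE 0.116, adjusted p = 0.09). When adjusted over the list alone, 5 fell and 1 rose. The list's mean was -0.07 and its median 0.01, and it did not pass camera (adjusted p = 0.574). Of 18 genes of lipid storage and synthesis, 1 fell, Dgat2, an enzyme of triglyceride synthesis (log2 fold change -0.39, SE 0.08, adjusted p = 0.027), and it was also the 1 member that fell when adjusted over the list alone. That list did not pass camera (adjusted p = 0.519). Of 8 genes of cholesterol synthesis, 7 had negative fold changes and none was called over all genes or over the list alone (camera adjusted p = 0.115). That list passed fry in the downward direction (fry adjusted p = 0.00412), which tests another question than camera. Its camera adjusted p was 0.436 with an estimated correlation. Insig1 was the member with the smallest p (log2 fold change -0.50, SE 0.175, adjusted p = 0.145).

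Of 18 sarcomere genes, which encode the contractile filaments, 4 fell in db/db hearts and none rose, 7 fell when adjusted over the list alone, and 17 fold changes were negative with a mean of -0.20. Tnnc1, cardiac troponin C, fell from 1137 ± 127 to 830 ± 45.2 FPKM (log2 fold change -0.45, SE 0.075, adjusted p = 0.0108). Myl3 fell by 0.36 (SE 0.066), Myl2 by 0.36 (SE 0.086) and Mybpc3 by 0.33 (SE 0.062) on the log2 scale. The sarcomere list passed camera (adjusted p = 7.11e-05), and its adjusted p was 0.436 with an estimated correlation. Beside this, transcripts of the mitochondrial genome took 43.6% ± 1.23 of FPKM in db/db and 39.5% ± 3.76 in db/+ hearts (SD, n = 5, exact two-sided permutation p = 0.0317). The db/+ 5 library was lowest at 33.5%, with 38.7% to 43.3% in the other db/+ libraries and 42.0% to 44.7% in db/db. Part of the gap thus rests on db/+ 5.

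The 13 mitochondrially encoded genes all had positive fold changes with a mean of 0.23, and none was called over all genes or over the list alone. The member with the smallest p was mt-Nd5, at 6333 ± 933 FPKM in db/+ and 7915 ± 701 FPKM in db/db (log2 fold change 0.33, SE 0.103, adjusted p = 0.112). The list passed camera (adjusted p = 2.34e-06), and its adjusted p was 0.436 with an estimated correlation. With quantile normalization it did not pass. Of 25 nuclear genes of oxidative phosphorylation, 1 fell, Cox7a1, a subunit of cytochrome c oxidase (log2 fold change -0.27, SE 0.055, adjusted p = 0.027), 1 fell when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.29).

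Of 16 genes of the endoplasmic reticulum stress response tested, 3 fell in db/db hearts and none rose, 5 fell when adjusted over the list alone, and the mean was -0.24. Chac1, which degrades glutathione and is induced in this response, fell from 3.31 ± 0.798 to 1.31 ± 0.34 FPKM (log2 fold change -0.89, SE 0.141, adjusted p = 0.00844). Sdf2l1 and the chaperone gene Calr fell by 0.83 (SE 0.196) and 0.41 (SE 0.083) on the log2 scale. The list passed camera (adjusted p = 0.00424), and its adjusted p was 0.436 with an estimated correlation. Of 12 glucocorticoid response genes tested, 2 rose and none fell, 6 rose when adjusted over the list alone, 8 fold changes were positive, and the mean was 0.28. Tsc22d3, a classic glucocorticoid-induced gene, rose from 24.1 ± 3.41 to 35.3 ± 5.89 FPKM (log2 fold change 0.53, SE 0.122, adjusted p = 0.044), and Cdkn1a, a cell cycle inhibitor, from 13.6 ± 4.93 to 30.2 ± 9.40 FPKM (log2 fold change 1.098, SE 0.263, adjusted p = 0.0484). That list passed camera (adjusted p = 0.00479), and its adjusted p was 0.482 with an estimated correlation.

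Of 20 genes of calcium handling and ion channels, 2 fell, Kcnip2 and the pacemaker channel gene Hcn2 (log2 fold change -0.51, SE 0.121, adjusted p = 0.0474). When adjusted over the list alone, 3 fell and 1 rose, and the list did not pass camera (adjusted p = 0.698). Of 18 genes of antioxidant defence, 1 rose, Cat, which encodes catalase, from 81.1 ± 6.81 to 110 ± 6.02 FPKM (log2 fold change 0.44, SE 0.068, adjusted p = 0.00782). When adjusted over the list alone, 1 rose and 2 fell, and the list did not pass camera (adjusted p = 0.115). Hmox1, heme oxygenase, had 15.1 ± 7.83 FPKM in db/+ and 6.29 ± 1.61 FPKM in db/db (adjusted p = 0.0558). None of 27 genes of extracellular matrix and fibrosis was called over all genes or over the list alone (camera adjusted p = 0.115). Leaving out db/+ 2 moved that list past the threshold (camera adjusted p = 0.000521), and leaving out db/+ 1 turned its mean from 0.03 to -0.07. None of 9 genes of the hypertrophy and fetal program was called over all genes or over the list alone. Nppa, atrial natriuretic peptide, had 1186 ± 356 FPKM in db/+ and 1621 ± 565 FPKM in db/db (adjusted p = 0.387), Nppb a log2 fold change of 0.51 (SE 0.291, adjusted p = 0.359) and Myh7 one of -0.28 (SE 0.147, adjusted p = 0.316). That list's mean was 0.03 and its median -0.03 (camera adjusted p = 0.778).

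None of 16 circadian clock genes was called over all genes. The members with the smallest p were Nr1d2, Per3 and Clock, with log2 fold changes of -0.54 (SE 0.136, adjusted p = 0.0561), -0.64 (SE 0.163, adjusted p = 0.0583) and 0.44 (SE 0.117, adjusted p = 0.0661). When adjusted over the list alone, 3 fell and 1 rose (camera adjusted p = 0.457). None of 8 inflammation genes was called over all genes, while 1 rose and 2 fell when adjusted over the list alone. The chemokine genes Ccl7 and Ccl2 had log2 fold changes of -1.19 (SE 0.396, adjusted p = 0.128) and -0.96 (SE 0.339, adjusted p = 0.149). The mean of that list was -0.13, its median 0.14 and the direction of camera upward (adjusted p = 0.574). None of 9 interferon response genes was called over all genes or over the list alone. Their mean was -0.01 with an upward direction in camera (adjusted p = 0.789), and the mean turned positive with other scalings.

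Markers of other cell types of the heart were measured in the same way. All 8 fibroblast markers had positive fold changes with a mean of 0.32. None was called over all genes, and 6 rose when adjusted over the list alone. Lum, lumican, had 36.8 ± 9.11 FPKM in db/+ and 55.0 ± 8.42 FPKM in db/db (log2 fold change 0.59, SE 0.158, adjusted p = 0.0721), and Gsn, gelsolin, a log2 fold change of 0.46 (SE 0.114, adjusted p = 0.0534). The list passed camera (adjusted p = 1.52e-05), and its adjusted p was 0.315 with an estimated correlation. All 6 markers of atrial cardiomyocytes had positive fold changes with a mean of 0.49 and none was called over all genes or over the list alone (camera adjusted p = 0.0142; adjusted p = 0.502 with an estimated correlation). Leaving out db/+ 2 or db/db 3 ended that list's call. None of the 10 endothelial or 11 macrophage markers was called over all genes or over the list alone (camera adjusted p = 0.516 and 0.862). The macrophage mean was -0.04 with an upward direction in camera. Of 8 smooth muscle and pericyte markers, 1 fell, Abcc9, a subunit of ATP-sensitive potassium channels that cardiomyocytes also express (log2 fold change -0.41, SE 0.094, adjusted p = 0.0436), also the 1 fall when adjusted over the list alone (camera adjusted p = 0.519). The 5 red blood cell genes had a mean of 0.90 and the 4 mesothelium genes one of 0.56, with none called over all genes or over the list alone (camera adjusted p = 0.0795 and 0.0531). The paralogs Hba-a1, Hbb-bs and Hbb-bt of the first list can share reads.

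Of 10 white adipocyte markers, 1 fell over all genes, while 1 rose and 1 fell when adjusted over the list alone. Cfd, the adipocyte-secreted complement factor D, fell from 52.3 ± 42.3 to 5.46 ± 4.91 FPKM (log2 fold change -2.89, SE 0.656, adjusted p = 0.0411). Adipoq, adiponectin, had 16.8 FPKM in db/+ and 7.41 FPKM in db/db on average (log2 fold change -0.89, SE 0.659, adjusted p = 0.489) and ranged from 1.92 to 32.6 FPKM over the 10 hearts. The list did not pass camera (adjusted p = 0.635). With the mitochondrial share of FPKM as a covariate, neither Cfd (log2 fold change -2.30, SE 0.833, adjusted p = 0.208) nor Cyp2e1 (-1.65, SE 0.529, adjusted p = 0.152) was called. Both stayed called with a score of adipocyte markers as a covariate (adjusted p = 0.000993 and 0.0136).

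**Figure D2:**
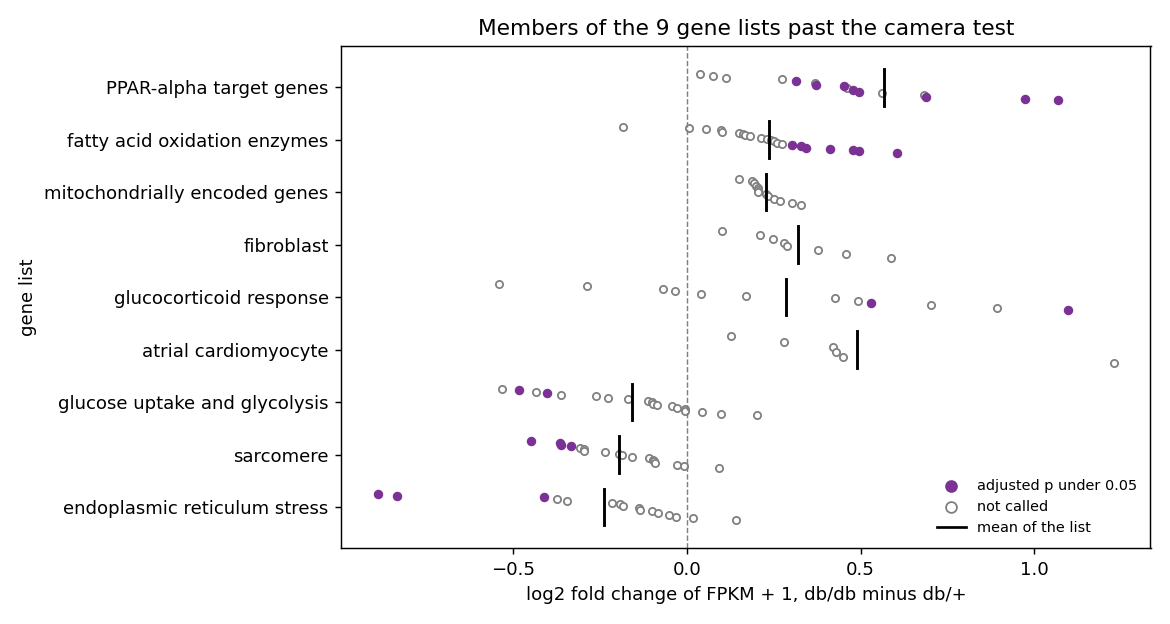
Log2 fold changes (db/db minus db/+, horizontal axis, of FPKM + 1) of the tested members of the 9 gene lists that passed camera with the preset correlation. Filled points are genes called over all genes, open points are not called, and the black line is the mean of the list, from 0.57 for PPAR-alpha target genes to -0.24 for endoplasmic reticulum stress. The means are over all tested members, and 1 PPAR-alpha target gene is not drawn. With an estimated correlation 0 of the 9 lists passed.

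None of the genes that write, erase or read m6A was called between genotypes, over all genes or over the lists alone. Of the 9 writers, Mettl3, the catalytic subunit of the methyltransferase complex, had 2.04 ± 0.199 FPKM in db/+ and 1.76 ± 0.321 FPKM in db/db hearts (log2 fold change -0.14, SE 0.092, adjusted p = 0.42). Mettl14, its partner, had a log2 fold change of 0.02 (SE 0.076), Wtap of 0.05 (SE 0.078), Virma of -0.08 (SE 0.062), Zc3h13 of -0.13 (SE 0.096) and Cbll1 of 0.06 (SE 0.082). Mettl16, a separate methyltransferase, had a log2 fold change of -0.14 (SE 0.077), and Rbm15 and Rbm15b had -0.05 (SE 0.098) and -0.02 (SE 0.084). The erasers Fto and Alkbh5 had log2 fold changes of 0.03 (SE 0.066, adjusted p = 0.855) and -0.05 (SE 0.07, adjusted p = 0.727), with 12.8 ± 0.964 FPKM of Alkbh5 in db/+ and 12.3 ± 0.906 FPKM in db/db. Of the 7 readers tested, Ythdf3 had the largest fold change, 0.22 (SE 0.147, adjusted p = 0.45), and Hnrnpa2b1 the smallest p, at -0.14 (SE 0.064, adjusted p = 0.264). Ythdf1, Ythdf2 and Hnrnpc had log2 fold changes of -0.07 (SE 0.074), -0.14 (SE 0.092) and -0.14 (SE 0.079). Ythdc1 and Ythdc2 lay at -0.002 (SE 0.088) and 0.02 (SE 0.096). Igf2bp2 lay under the FPKM limit, at 0.694 ± 0.0961 in db/+ and 0.644 ± 0.15 in db/db. Writers and readers did not pass camera (adjusted p = 0.698 and 0.66).

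The number and length of m6A peaks did not differ between genotypes by more than the spread between hearts. A heart had 14870 ± 3007 distinct peaks in db/+ and 13500 ± 2897 in db/db (SD, n = 5; exact two-sided permutation p = 0.524), a difference smaller than the spread between animals. Distinct peaks of a heart can overlap, so they are not separate sites. Merged where they overlapped, they made 6737 ± 1676 regions per heart in db/+ and 5968 ± 1437 in db/db (exact two-sided permutation p = 0.532). Peaks fell in 4834 ± 850 genes in db/+ and 4440 ± 931 genes in db/db hearts (exact two-sided permutation p = 0.54). The median peak length was 192 ± 15.7 bp and 198 ± 15.2 bp of exon (exact two-sided permutation p = 0.643). Both extremes were single hearts: db/+ 5 had 20021 peaks and db/db 5 had 8462. Without both of them, chosen after seeing the data, db/db hearts had 1178 peaks more than db/+ hearts (exact two-sided permutation p = 0.143), so the direction turned. The same happened to the genes with a peak, 373 more in db/db (exact two-sided permutation p = 0.114).

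Most peaks lay in coding sequence or the 3′ untranslated region. Peaks within coding sequence alone made up 41.7% ± 4.24 in db/+ and 45.3% ± 3.15 in db/db hearts (SD, n = 5; exact two-sided permutation p = 0.175). Peaks within the 3′ untranslated region alone made up 38.1% ± 5.38 and 33.5% ± 1.76 (exact two-sided permutation p = 0.0635), and peaks over both made up 17.4% ± 1.70 and 17.4% ± 1.49 (exact two-sided permutation p = 0.952). Peaks with sequence of the 5′ untranslated region were the smallest class, 3.19% ± 0.71 in db/+ and 4.24% ± 0.72 in db/db (exact two-sided permutation p = 0.0476). Adjusted over the 4 classes, chosen after seeing the data, that p was 0.127. Single hearts weighed on these gaps. The heart db/+ 5 had 47.2% of its peaks within the 3′ untranslated region alone, against 33.4% to 37.7% in the other db/+ hearts. For the 5′ untranslated region, db/+ 5 had the lowest share of all hearts, 2.23%, and db/db 1 the highest, 5.43%. That gap was 0.82 points without db/+ 5 and 0.76 without db/db 1 (exact two-sided permutation p = 0.0952 and 0.119, unadjusted). It kept its direction in every setting tried. With overlapping peaks merged it was 1.39 points, and with equal numbers of top peaks 1.19 (exact two-sided permutation p = 0.0159 and 0.0714, unadjusted).

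**Figure D3:**
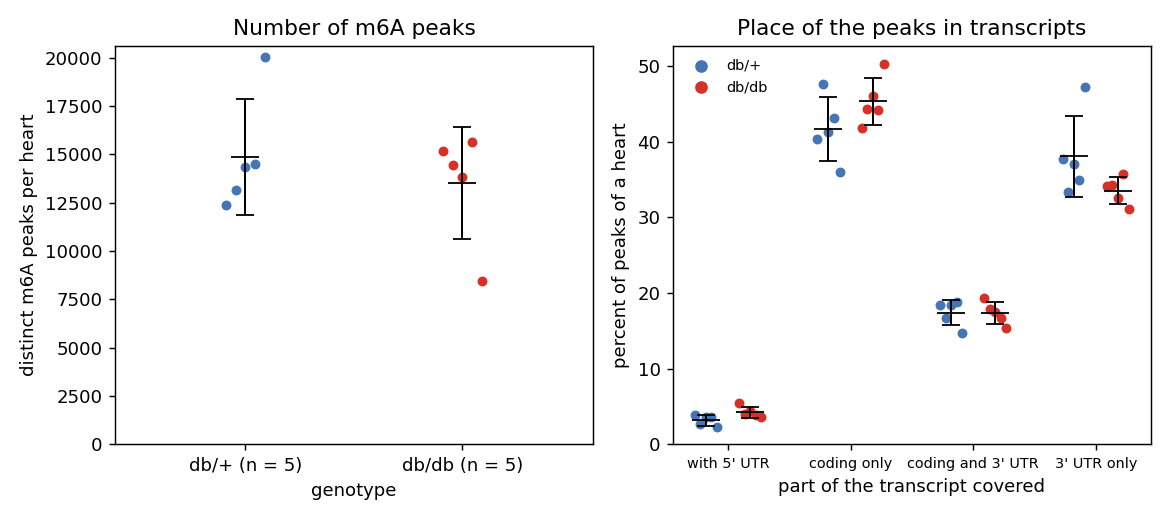
Distinct m6A peaks per heart (left panel, vertical axis from 0) and the percent of a heart's peaks by the part of the transcript they cover (right panel). Points are single hearts (5 db/+ in blue, 5 db/db in red), bars are means and whiskers SDs. The numbers overlap between genotypes (12385 to 20021 in db/+ and 8462 to 15607 in db/db), with both extremes in single hearts.

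Merging the peaks of all hearts that overlapped by at least 1 bp of exon on the same strand gave 15747 regions. Of these, 2268 regions (14.4%) had a peak in all 10 hearts and 6167 (39.2%) in 1 heart. A peak in at least 4 hearts of one genotype and at most 1 of the other was found in 266 regions, 91 gained and 175 lost in db/db. This balance depends on db/db 5, the heart with the fewest peaks: with 3 of 4 hearts enough in a genotype with 1 left out, it turned to 305 gained and 201 lost without db/db 5, and to 508 gained and 265 lost without db/+ 5 and db/db 5, a setting chosen after the data were seen. No region passed Fisher's exact test after adjustment over all regions, 106 passed it at an unadjusted p under 0.05, and the smallest unadjusted p that 5 against 5 hearts allow is 0.00794. Over 15747 regions that p could pass only if a large part of the regions reached it. The lack of passing regions is therefore no evidence that the genotypes are alike. Regions with a peak in all hearts of one genotype and none of the other numbered 9, 3 gained and 6 lost. Of 100 splits of the hearts into 5 and 5, the real one included, 16 gave at least 266 differing regions.

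The 3 gained regions of 5 hearts against 0 lay in Zfp27, Agpat3 and Nudcd1, in coordinates that fit GRCm38. That of Zfp27, a zinc finger gene, covered coding sequence on chromosome 7 from 29896109 to 29896355 (minus strand), with a mean authors' fold enrichment of 9.07. That of Agpat3, an acyltransferase of phospholipid synthesis, lay in the 3′ untranslated region on chromosome 10 from 78269567 to 78269925 (minus strand), and that of Nudcd1 in the 5′ untranslated region on chromosome 15 from 44428188 to 44428307 (minus strand). Gained in 4 hearts against 0 were coding sequence of Pkd2, which encodes polycystin-2 (chromosome 5, 104459840 to 104466917, plus strand, across an intron), the 3′ untranslated region of Apopt1 (chromosome 12, 111734072 to 111734220, plus strand) and the 5′ untranslated region of Irf2bp1 (chromosome 7, 19004133 to 19004430, plus strand).

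The 6 lost regions of 5 hearts against 0 lay mostly in 3′ untranslated regions. They were in Podxl, podocalyxin (chromosome 6, 31519488 to 31519936, minus strand), Abcc9 (chromosome 6, 142589539 to 142589961, minus strand), Gfm2 (chromosome 13, 97176292 to 97176451, plus strand), the splicing regulator Mbnl2 (chromosome 14, 120431547 to 120431697, plus strand) and the chemokine receptor gene Ackr3 (chromosome 1, 90215085 to 90215710, plus strand). That of Dcun1d5 spanned coding sequence and 3′ untranslated region (chromosome 9, 7206890 to 7207100, plus strand). Each of these regions had an unadjusted Fisher's exact p of 0.00794. Of the 11 genes with a named region that were tested for expression, Abcc9 was the one called, lower in db/db. Agpat3 had a log2 fold change of 0.27 (SE 0.095, adjusted p = 0.152), Podxl of -0.10 (SE 0.099), Mbnl2 of 0.05 (SE 0.191) and Ackr3 of -0.17 (SE 0.121).

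**Figure D4:**
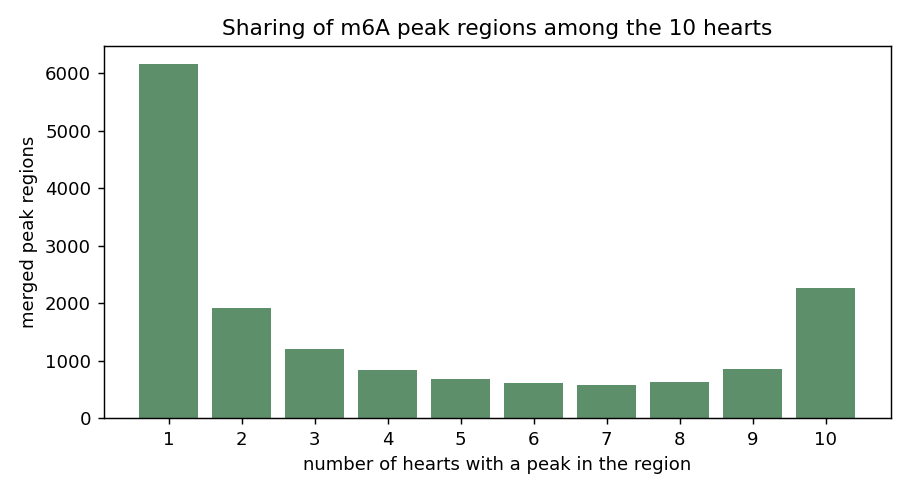
Number of merged m6A peak regions (vertical axis) by the number of the 10 hearts with a peak in the region (horizontal axis). The largest groups are the 6167 regions seen in 1 heart and the 2268 seen in all 10.

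Peak lists of hearts with the same genotype were not measurably more alike than lists of different genotypes. The mean Jaccard index, the shared share of covered exon bases, was 0.498 within and 0.493 between genotypes (difference 0.00508, exact one-sided permutation p = 0.214). With the same number of top peaks taken from each heart the difference was 0.0108 (exact one-sided permutation p = 0.0476), and without db/+ 5 and db/db 5 it was 0.0122 (exact one-sided permutation p = 0.0286). Leaving out db/+ 5 alone turned it to -0.000737.

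The 82 genes with gained m6A regions only had a mean log2 fold change of 0.07 and a median of 0.02, against a mean of -0.02 for the other genes with a peak region, with 5 called up and 1 called down (limma cameraPR, adjusted p = 0.0282). Those called up included Tfrc and Chrna2 (log2 fold changes 1.73 and 1.31). Each had a region gained in its 3′ untranslated region, in 4 db/db hearts and 0 db/+ hearts. Whether a higher transcript level itself led to such peaks being called was not tested for this set, so its rise may partly reflect how it was chosen. The 165 genes with lost regions only had a mean of -0.04 and a median of -0.03, with 2 called up and 5 called down (adjusted p = 0.867). The background was 7480 tested genes with a peak region in at least 1 heart. With peaks joined only at the larger overlap tried, the gained genes did not pass (mean 0.06, median -0.007, adjusted p = 0.122). They passed cameraPR with a pseudocount of 0.1 (adjusted p = 0.0303) and with a replicate block (adjusted p = 0.0333). They also passed a test against random gene sets of matched mean FPKM (adjusted p = 0.0004), which takes genes as independent. Of 100 splits of the hearts, the real one included, 6 gave a p as small.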

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

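The tests of splits for called genes and for peak regions, and those of adipose tissue, of the mitochondrial gap and of the share of cardiomyocytes, were chosen after the results they bear on had been seen. For the others the expected outcome was written down before the test was run. The rescaling of the nuclear total is one of these, although the rescaling itself was added after the called genes had been seen.

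For the genes called between genotypes, 1 of 100 splits of the hearts, the real one, gave as many as 311, and the highest of the other splits gave 6. This argues against a chance division of the hearts for that count, though 1 in 100 is the least that 100 splits can give. It does not bear on factors that differ along with the genotype, such as the mitochondrial share. For the gene lists, 32 of 100 splits gave at least the 9 lists that passed camera and the highest other split gave 16, so chance is not excluded for the number of lists with the preset correlation. List by list, 1 of 100 splits gave a camera p as small for PPAR-alpha target genes, 3 each for fatty acid oxidation enzymes and the fibroblast markers, 9 for endoplasmic reticulum stress, 11 for the sarcomere, 12 for glycolysis, 15 for the mitochondrially encoded genes, 18 for the glucocorticoid response and 23 for the atrial cardiomyocyte markers. For the differing peak regions, 16 of 100 splits gave at least 266, with up to 326 in the others, so chance is not excluded. For the expression of genes with gained or lost regions, 6 of 100 splits gave a p as small as the real 0.0141, and the smallest p of the other splits was 2.89e-06, so chance is not excluded there either.

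Cfd and Cyp2e1, both abundant in fat, were lower in db/db hearts. Less adipose tissue around the db/db hearts as the whole cause is argued against by a fit with the mean of Adipoq, Plin1, Cidec and Car3 as a covariate, in which Cfd kept a log2 fold change of -2.10 (SE 0.187) and Cyp2e1 one of -1.59 (SE 0.255). With the mitochondrial share as a covariate, Cfd went from -2.89 (SE 0.656) to -2.30 (SE 0.833) and Cyp2e1 from -2.03 (SE 0.417) to -1.65 (SE 0.529), and both calls ended as the folds shrank and the errors rose. That gap and the genotype cannot be told apart for these genes, since the share itself differs between genotypes. The genotype itself stays open, and no biological explanation was tested.

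The called sarcomere transcripts, 4 of 18, were lower in db/db hearts. A larger part of each library taken by mitochondrial transcripts is argued against as the whole cause: with those genes removed and the nuclear total set equal, Mybpc3 still had a log2 fold change of -0.30 (SE 0.063), the least negative of the 4 called members, and the mean of the list went from -0.20 to -0.16. For a lower share of cardiomyocytes, the outcome looked for was an equal rise of the markers of all other cell types. The fibroblast markers rose against the endothelial markers by 0.26 (exact two-sided permutation p = 0.0238) and against the macrophage markers by 0.36 (exact two-sided permutation p = 0.0159). The gap to smooth muscle markers was 0.20 (exact two-sided permutation p = 0.175). The rise was thus not equal over all these markers. This cannot decide on the share of cardiomyocytes, since more fibroblasts alone would also lower it. A lower share of cardiomyocytes and more fibroblasts in db/db hearts stay open, and so does chance for the list as a whole. The genotype itself stays open as well, untested.

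With the same number of top peaks taken from each heart, 192 regions differed between genotypes, 81 gained and 111 lost. Of 100 splits 1, the real one, gave as many, with 176 the highest of the others, a count chosen for mention after it was seen, while 33 of 100 gave as many as the 191 regions from peaks above the median fold, 32 of 100 as many as the 148 genes with a peak gained or lost, and 1 of 35 as many as the 773 regions without db/+ 5 and db/db 5. For the equal lists, transcript level as the setter of which peaks are called was examined through regions in genes that changed by less than 0.2 on the log2 scale. In such genes 128 regions differed, 3 splits of 100 gave as many, and the highest other gave 145. Fewer splits did so than the limit set beforehand. This cannot exclude transcript level, since smaller changes remain in these genes and other splits reached higher counts. Above an SD of 0.4, 6 of 10 peak lists also matched the expression of their own animal best. The count over all peaks was within chance, and how the depth of the libraries bears on which peaks rank high stays open, since it is unknown. With 3 of the 5 selections of peaks within chance, no explanation is offered.

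In groups of 5 hearts, 300 were searched for a heart far from the other 4, which chance gives to about 1 in 20 of them, or 15, and 18 were found. A pair of hearts was found for their peak lists: db/+ 5 had 20021 distinct peaks in 6281 genes, against at most 14483 and 4750 in the other db/+ hearts, and db/db 5 had 8462 peaks in 2819 genes, against at least 13821 and 4540 in the other db/db hearts. The heart db/+ 5 also had the highest FPKM of its genotype for Myl4 (112 against at most 64.3), Dkk3 (34.2 against 22.3) and Lep (0.629 against 0.082), and db/db 5 the lowest for Dcn (112 against at least 136) and Vwf (5.77 against 10.7). In db/+ 2, Lox (3.55 FPKM), Irf7 (2.27 FPKM) and Adgre1 (7.04 FPKM) were far above and Mettl16 (1.33 FPKM) far below the other db/+ hearts. In db/db 1, Mettl3 (1.20 FPKM) and Gclm (0.812 FPKM) were far below the other db/db hearts. Tfrc was highest in db/db 3 (32.5 FPKM against at most 17.4), Vsig4 lowest in db/+ 1 (2.19 FPKM against at least 3.62), and Cyp1a1 was above 0 in db/db 4 alone among db/db hearts (0.071 FPKM).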

How the results depend on the processing

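The fits without db/+ 5 and db/db 5, with the adipocyte or mitochondrial covariate and with equal nuclear totals were chosen after seeing the data. Of the 44 called genes among the 139 named ones, none changed sign in any setting, 30 stayed called whichever single library was left out, and 28 stayed called with the mitochondrial covariate. The count of 311 called genes became 189 with the adipocyte covariate, 137 with the mitochondrial covariate and 69 with a 1.5-fold limit, which the limit itself brings about. Without single libraries it was 112 (db/db 3) to 315 (db/+ 5), and below 311 by more than 1.5 times also without db/+ 1 (202), db/+ 3 (121), db/+ 4 (165), db/db 1 (127), db/db 2 (153) and db/db 4 (173), where fewer samples were tested. Array weights gave 454. Calls split as 164 rises and 132 falls with quantile normalization, 161 and 113 with equal medians and 155 and 113 with equal nuclear totals, against 133 and 178. With a replicate block 72 genes were called, 30 rises and 42 falls. Animals with the same number did not deviate together (correlations 0.028, -0.02, -0.078, -0.026 and -0.105, own number best for 0 of 5), so the numbers are no evidence of a pairing. The blocked permutation of peak measures cannot reach the threshold with 5 numbers, so it says nothing of their stability.

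The number of gene lists past camera was 0 with an estimated correlation, also with the replicate block. With fry, which tests another question, 7 lists passed. Cholesterol synthesis was among these 7, and the mitochondrially encoded, glucocorticoid and atrial lists were not. The PPAR-alpha, fatty acid oxidation, glycolysis, sarcomere, endoplasmic reticulum stress and fibroblast lists passed in the 16 of 18 settings without an estimated correlation. The mitochondrially encoded, glucocorticoid and atrial lists passed in 14, 15 and 13. The mean of interferon genes turned positive with a pseudocount of 0.1 (0.008), quantile normalization (0.018), equal medians (0.023) and no db/+ 5 and db/db 5 (0.067). The macrophage mean was 0.07 without these 2, and the antioxidant mean -0.002 with a pseudocount of 0.1. Without single libraries the means ranged from -0.037 to 0.117 for hypertrophy, -0.068 to 0.178 for extracellular matrix, -0.2 to 0.028 for inflammation, -0.102 to 0.048 for interferon, -0.022 to 0.085 for antioxidant defence and -0.131 to 0.096 for macrophages. Genes near 0 changed sign: with the mitochondrial covariate Rbm15 (0.021), Rbm15b (0.066), Cbll1 (-0.011), Alkbh5 (0.027), Ythdc2 (-0.118), Srebf2 (0.006) and Rgs5 (-0.023). With the adipocyte covariate these were Rbm15b (0.022), Ythdc1 (0.022) and Ythdc2 (-0.045). Without db/+ 5 and db/db 5 they were Rbm15b (0.054), Ythdc1 (0.024) and Ythdc2 (-0.017), with equal medians Rbm15b (0.007) and Ythdc1 (0.028), with quantile normalization Ythdc1 (0.025) and with array weights Ythdc2 (-0.007). Without single libraries Mettl14 ranged from -0.01 to 0.062, Wtap from -0.001 to 0.09, Rbm15b from -0.062 to 0.018, Ythdc1 from -0.051 to 0.045 and Ythdc2 from -0.043 to 0.065.

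Without db/+ 5 and db/db 5 the differences turned to 1178 peaks (p = 0.143) and 373 genes with a peak (p = 0.114, exact permutation) more in db/db. Without single hearts the gap in peaks, -1370 over all hearts, ranged from -1990 (db/+ 1) to -81.5 (db/+ 5), with -110 without db/db 5, and the gap in genes from -565.6 (db/db 4) to 11.2 (db/db 5). Peak length kept its direction in all settings. List similarity passed the threshold with equal numbers of top peaks (0.0108) and without both of these hearts (0.0122), and ranged from -0.000737 (without db/+ 5) to 0.0077 (without db/+ 4). Differing regions numbered 9 at 5 against 0 hearts, 148 as genes with any peak, 773 without both of these hearts and 406 (without db/+ 5) to 524 (without db/+ 1) without single hearts, where 3 of 4 hearts were enough, which makes the rule easier. Gained regions outnumbered lost ones without db/db 5, 305 to 201, and without both of these hearts, 508 to 265. Genes with gained regions did not pass at 5 against 0 (2 genes, mean 0.24) or with the larger overlap (mean 0.057). The cause was not tested except where one is given. The unknown depth limits what low values and missing peaks can show.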

Other observations

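The lists of this part and the genes named in it were picked after the called genes had been seen, and each list was then tested on its members that were not called. Genes of protein folding and of mitochondrial translation were among the falls. Of 20 heat shock chaperone genes tested, 5 fell in db/db hearts: Stip1, Fkbp4, Hspe1, Hsp90ab1 and Hspa4l, with log2 fold changes from -0.43 (SE 0.073) for Stip1 to -0.30 (SE 0.052) for Hsp90ab1, one of the most abundant chaperones, at 329 FPKM in db/+ and 268 in db/db. Of 78 mitochondrial ribosomal protein genes, 7 fell and none rose, with the largest change among these 7 in Mrpl21 (log2 fold change -0.39, SE 0.071). Of 23 genes of amino acid breakdown, 6 fell and none rose: Gcat, Abat (log2 fold change -0.69, SE 0.123), Ppm1k (-0.55, SE 0.109), which activates the breakdown of branched-chain amino acids, Acy1, Gcdh and Aldh4a1. Among 14 FoxO target genes tested, 4 fell and none rose. Fbxo32, a ubiquitin ligase of muscle wasting, Ulk1, Klhl38 and Tcp11l2 fell by 0.62 (SE 0.126), 0.47 (SE 0.067), 0.72 (SE 0.14) and 0.77 (SE 0.136) on the log2 scale. Among 14 hypoxia response genes tested, 4 rose and none fell. Beside Tfrc, these were Egln3, Adm and Stc2, which rose by 0.79 (SE 0.124), 0.70 (SE 0.16) and 0.36 (SE 0.077).

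Whether these changes belong to a wider shift was tested on the members not called. The 71 other mitochondrial ribosomal protein genes (58 of them negative, mean -0.10), the 15 other chaperone genes (all 15 negative, mean -0.21) and the 17 other genes of amino acid breakdown (15 negative, mean -0.18) each passed camera with an adjusted p of 0.000699. With an estimated correlation the adjusted p was 0.223 for each, and with fry, which tests another question, it was 0.033 for each. Of 100 splits of the hearts, 24, 19 and 25 gave a camera p as small. A general fall of these groups may thus be present but cannot be told apart from chance. For a lower FoxO response the 10 other members had a mean of -0.15 (camera adjusted p = 0.0624), and for a hypoxia response the 10 other members had a mean of 0.06 (adjusted p = 0.095). Both miss the threshold with the sign of the called members, and 38 and 22 of 100 splits gave a p as small. The outcome written down beforehand for each response was thus not met, and neither response is shown or excluded. Genes with a peak in all 10 hearts (2087) were set against genes without any peak (2833) at matched mean FPKM: the gap was 0.054 ± 0.062 in db/+ and 0.074 ± 0.056 in db/db (log2, SD, n = 5; exact two-sided permutation p = 0.595), so a level shift of m6A-bearing transcripts was not found and one smaller than this spread stays open.

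Some genes of fat cells are given as values. Lep, which encodes leptin, was listed at 0 in 2 db/+ hearts and at 0.035, 0.082 and 0.629 FPKM in the others, against 1.00, 4.02, 0.343, 7.14 and 1.40 FPKM in the db/db hearts (log2 fold change 1.44, SE 0.409, adjusted p = 0.086), while Cfd was lower in db/db and Fabp4 had a log2 fold change of 0.05 (SE 0.095). Pdk4, a PPAR-alpha target gene, had 88.6 FPKM in db/+ 5 and 399 to 563 FPKM in the other 9 hearts. The Y-linked gene Ddx3y was read in all 10 hearts, from 11.8 to 19.7 FPKM.

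Peak lists were assigned to animals by the animal number in the names of their sheets. To check this, peak lists and expression values were set against each other through the genes whose presence of a peak varied between hearts. Over 3523 such genes, 0 of 10 peak lists matched the expression of their own animal best (exact permutation p = 0.812 within genotypes). Over the 168 genes with an SD above 0.4 on the log2 scale, 6 of 10 did (exact permutation p = 0.00215), and over the 1044 with an SD above 0.2, 4 of 10 did (exact permutation p = 0.0138). A heart of their own genotype was the best match for 9, 10 and 10 of 10 lists with no limit, above 0.2 and above 0.4. The check thus bears out the genotype of nearly all lists better than the single animal within a genotype, which the comparisons between genotypes do not need. The limits were chosen after the first result had been seen.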
